A study of Mus musculus with 29 samples.

How the data were processed

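Gene expression in whole atria of male mice was measured by RNA sequencing of 29 libraries in 6 groups. Per the labels' protocols, RNA was extracted with a miRNeasy micro kit, at least 500 ng entered a stranded poly-A selected TruSeq mRNA preparation, and mice stayed on the high-fat diet for 4 weeks from 5 weeks of age. Per the submitters' processing notes, FastQC 0.11.7, STAR 2.7.6a and featureCounts 2.0.1 were used with builds GRCm38 and mm10. The deposited values are raw counts of read pairs per gene name, made by the authors with featureCounts 2.0.1, per the file headers. Per the same headers, strand was not used in counting, and pairs that map to several places or lie over more than 1 gene were left out. Genes that overlap on opposite strands, and genes with near-identical copies, are therefore uncertain. How reads were trimmed or merged before counting is not given in the sources used here. The annotation held an added record named flag of 717 bases, which had 0 counts in all 29 libraries; what it stands for is not given in the sources used here. With 3 counts as the limit that a count of 0 allows, each library leaves room for a low level only, and such limits cover counting error alone.

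All 29 files held the same 55292 gene names, and no column was left without a sample. No pair of files was identical, and the closest pair within a group differed by 6.9 per gene in a chi-square test of counts, so no library was taken as deposited in duplicate. Total counts ranged from 13189995 to 33061018 per library. They were 16040262 to 30365131 in Ctrl_RD, 16159281 to 33061018 in Ctrl_HFD, 15318744 to 21343352 in NaV1.5_RD, 17272602 to 22181019 in NaV1.5_HFD, 15595556 to 23494222 in vehicle and 13189995 to 29177180 in NR. Groups, replicate numbers and batches come from the labels. Ctrl_RD replicate 1 and NaV1.5_RD replicate 4 carry no number in their titles, so their numbers are names only.

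Genes were tested with edgeR 4.0.16 (quasi-likelihood F-test, filterByExpr, TMM scaling, robust dispersion) in R 4.3.3. The tests were 2-sided, with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05 on the adjusted p. The SE given with a log2 difference is its absolute value divided by the square root of the F statistic. It is not a standard error of the fitted coefficient. The 4 diet groups formed one fit and the vehicle and NR groups another, each with group and batch as terms. Ctrl_HFD replicate 4 is the only library of the diet experiment labelled outside batch 1, so the batch term absorbs it. All vehicle libraries are in batch 3, and of the NR libraries replicates 1 to 5 are in batch 2 and replicates 6 and 7 in batch 3, so the batch 2 libraries inform only the spread. Normalised counts are CPM, per library total with TMM scaling, and principal components used log2 CPM with a prior count of 2. On simulated data with 50 changed genes at each fold, a 2-fold change was recovered for 70% of genes for the diet in NaV1.5 mice, 62% for genotype on regular diet, 70% for genotype on high-fat diet, 66% for the diet in control mice, 54% for the interaction and 62% for NR. For a 1.5-fold change these were 46%, 42%, 46%, 36%, 18% and 54%, in the same order. Counts were simulated independently between genes. The same simulation held 4-fold and 8-fold changes, which ease the adjusted threshold for smaller ones. Where few genes pass, recovery may be lower than these shares.

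Of 44 gene lists fixed before the data were examined, 43 had at least 5 measured members and were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. The same test was run with an estimated correlation, and its adjusted p stands beside each list described. The fry test was run as well, and its adjusted p is given for the 5 lists that pass it. The 4 sets tested under NR were adjusted over the 4. The lists described were chosen after their values were seen, from the lists that passed. For each comparison the genes named are the 12 with the smallest p in each direction among annotated genes past the threshold (5 where fewer than 5 passed, said not to have passed), up to 4 members of each described list with the smallest p, and 7 genes of NAD metabolism. Some genes that the rule takes in are not reported here. Hadhb, Parp14, Ddx3y, Drosha, Myl2, Ucp1 and Adipoq fall outside this rule and were named after their values were seen. Coordinates are those of GRCm38 in the count files.

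Alternatives fixed before the data were examined were DESeq2 size factors, no low-count filter and a stricter one (1 CPM), no batch term, batch 1 or batch 3 libraries alone, NR of batch 2 against vehicle, all 29 libraries in one fit, the replicate number as a block, DESeq2 1.42.0, limma-voom with quality weights, and each library left out in turn. Offsets for GC content and gene length were added after a trend with GC content was seen. Python 3.11.15 and matplotlib 3.10.9 were used for reading files and drawing.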

Results

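Polyadenylated RNA of whole atria from male mice was sequenced in 29 libraries that fall into 6 groups. In the first experiment, control mice and transgenic mice labelled NaV1.5 were kept on a regular diet (RD) or on a high-fat diet (HFD) for 4 weeks from 5 weeks of age. It holds 4 Ctrl_RD, 4 Ctrl_HFD, 4 NaV1.5_RD and 5 NaV1.5_HFD libraries. In the second experiment, NaV1.5 mice on HFD received vehicle (5 libraries) or nicotinamide riboside (NR, a precursor of NAD, 7 libraries). Total counts assigned to genes ranged from 13189995 to 33061018 per library, and mitochondrially encoded genes took 14.68 to 26.58% of them. Each library is taken as a separate sample of its group. The labels do not say that each came from a separate mouse, so p-values measure only the spread between these samples.

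The libraries of the 2 experiments, which also lie in different batches, were widely separated. The first principal component of log2 CPM carried 60.1% of the variance and the second 11%, and together they parted the libraries labelled batch 1, batch 2 and batch 3, with 1 exception. Ctrl_HFD replicate 4 is labelled batch 2 and lay at -57.58 on the first component, among the batch 1 libraries and far from the 5 NR libraries of batch 2, which lay between 92.67 and 99.9. Apart from that library and the 2 batches of NR, batch and experiment coincide and cannot be told apart. The Y-linked RNA helicase gene Ddx3y shows the size of the difference between batches in these male mice: 21.1 ± 8.61 CPM (SD, n = 16) in batch 1, 189 ± 3.94 CPM (n = 5) in the NR libraries of batch 2 and 108 ± 11.6 CPM (n = 7) in batch 3. Ctrl_HFD replicate 4 had 25.2 CPM. Comparisons were therefore made within each experiment with batch in the model. As a result Ctrl_HFD replicate 4 carries no weight in any contrast, and the NR contrast rests on 2 NR and 5 vehicle libraries of batch 3.

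**Figure D1:**
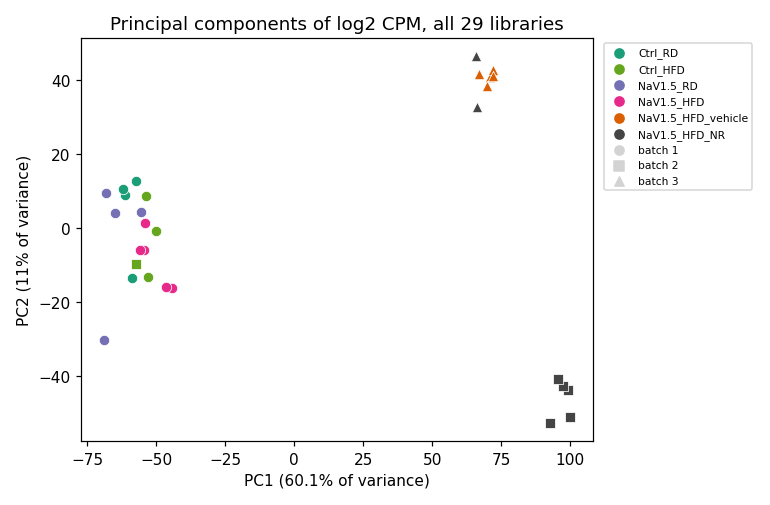
Principal components of log2 CPM of the 29 libraries, with PC1 (60.1% of variance) on the x axis and PC2 (11%) on the y axis; each point is 1 library, colours are groups and shapes are labelled batches. Ctrl_HFD replicate 4 (square among the circles) lies at -57.58 on PC1, with batch 1.

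The first question was what the transgene did on regular diet. A record named flag in the count files held 0 counts in every library. Cdh6, a cadherin of cell-to-cell adhesion (GRCm38 chromosome 15, 13028701 to 13173675, minus strand), was higher in NaV1.5 atria, at 10.7 ± 1.75 CPM (SD, n = 4) against 0.0584 ± 0.0683 CPM (n = 4). Its fitted log2 difference of 7.24 (SE 0.37, edgeR adjusted p = 4.65e-10) is imprecise because no Ctrl_RD library held more than 4 counts. With 1 library left out it ran from 6.8 to 8.09. Scn10a, which encodes the sodium channel NaV1.8 (chromosome 9, 119608456 to 119719322, minus strand), was lower, at 7.35 ± 2.04 CPM (n = 4) against 17.4 ± 1.81 CPM (n = 4). Its log2 difference was -1.25 (SE 0.18, adjusted p = 0.00632). These were the only 2 of 16168 tested genes that passed with edgeR. An unadjusted p below 0.05 was found for 988, where chance gives about 808, and DESeq2 called 27 genes and limma-voom 13. Leaving out NaV1.5_RD replicate 1 left 1 call, with Scn10a at an adjusted p of 0.0563, while leaving out NaV1.5_RD replicate 3 or NaV1.5_RD replicate 4 gave 5. Next in rank and not past the threshold were Fam81a at 2.08 (adjusted p = 0.0689) and the endothelial membrane gene Tmem100 at 0.57 (adjusted p = 0.078) among the higher genes. Among the lower were Gucy2e, a retinal guanylate cyclase, at -2.72 and Nav3 at -1.01 (both adjusted p = 0.165).

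**Figure D2:**
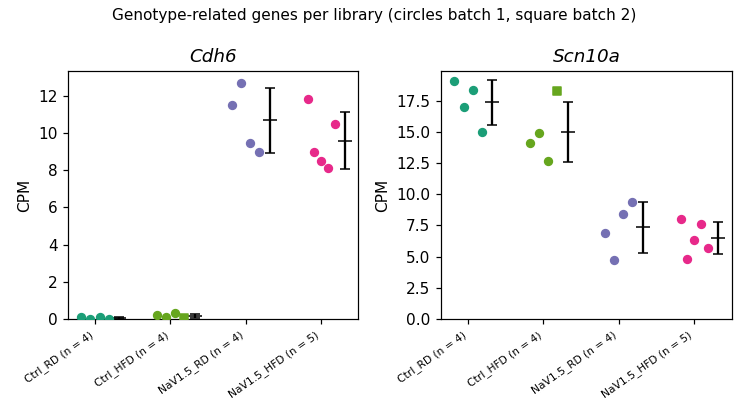
Normalised counts (CPM, y axes from 0) of Cdh6 and Scn10a in the 4 groups of the diet experiment; each point is 1 library and the bar is the mean ± SD. Cdh6 reaches 9 CPM or more in the 4 NaV1.5_RD libraries and at most 0.13 CPM in the 4 Ctrl_RD libraries.

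Of 43 gene lists tested on regular diet, 7 passed camera at its preset correlation. Nuclear genes of the respiratory chain lay higher in NaV1.5 atria as a group (51 measured, median log2 difference 0.21, camera adjusted p = 2.46e-10; adjusted p = 0.981 with an estimated correlation). Of these, 0 passed singly with edgeR, over all genes or adjusted over the list alone; 7 had an unadjusted p below 0.05, and DESeq2 and limma-voom each called 0. The leading members were Atp5l at 0.44 (SE 0.13) and Cox4i1 at 0.26 (SE 0.10), subunits of ATP synthase and cytochrome c oxidase. Among 39 ion channels and connexins the median was -0.14 (camera adjusted p = 0.01; adjusted p = 0.981 with an estimated correlation). Over all genes 1 fell (Scn10a), while adjusted over the list alone 1 fell and 1 rose. The 24 proliferation genes had a median of 0.32 (camera adjusted p = 0.00666; adjusted p = 0.981 with an estimated correlation), led by the cyclin gene Ccnb1 at 1.08 (SE 0.37). Markers of ventricular cardiomyocytes, a cell type outside the atria, were also higher in NaV1.5_RD (6 measured, median 0.41, camera adjusted p = 0.0462; adjusted p = 0.772 with an estimated correlation, fry adjusted p = 0.031). So were fibroblast markers (13 measured, median 0.17, camera adjusted p = 0.0354; adjusted p = 0.883 with an estimated correlation) and macrophage markers (18 measured, median 0.17, camera adjusted p = 0.0265; adjusted p = 0.981 with an estimated correlation). Without NaV1.5_RD replicate 4 the respiratory chain list had a median of 0.05 (adjusted p = 0.13) and the ion channel list of -0.07 (0.313). The respiratory chain list passed with lower medians of 0.10 with GC and length offsets and 0.12 with limma-voom. With the replicate number as a block, a fit that also left out the unnumbered libraries, that list failed (median 0.03, adjusted p = 0.694). Across genes the log2 difference in this comparison ran with gene length (rho -0.257), and with the offsets that rho was -0.0266. The ion channel list also failed without NaV1.5_RD replicate 1 (0.0836) or Ctrl_RD replicate 1 (0.133), and with GC and length offsets (0.124). The proliferation list had a median of 0.09 without NaV1.5_RD replicate 1 (0.511), 0.23 without Ctrl_RD replicate 2 (0.207) and 0.55 without Ctrl_RD replicate 3, where it passed. With all libraries in one fit it had an adjusted p of 0.0925. Single libraries and other settings ended the marker calls too. Ventricular markers failed without NaV1.5_RD replicate 1 (0.145), NaV1.5_RD replicate 2 (0.103), NaV1.5_RD replicate 3 (0.0834, median 0.27) or Ctrl_RD replicate 4 (0.182), with the offsets (0.0767) and with all libraries in one fit (0.0925). Fibroblast markers failed without NaV1.5_RD replicate 1 (0.177), NaV1.5_RD replicate 2 (0.0625), NaV1.5_RD replicate 3 (0.0853) or Ctrl_RD replicate 2 (0.207), without a low-count filter (0.0512) and with all libraries in one fit (0.0575). Macrophage markers failed without NaV1.5_RD replicate 1 (0.159), NaV1.5_RD replicate 2 (0.0787), NaV1.5_RD replicate 4 (0.0602, median 0.10), Ctrl_RD replicate 1 (0.556, median 0.06) or Ctrl_RD replicate 2 (0.207).

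On high-fat diet the same question gave 6 genes higher and 8 lower in NaV1.5 atria among 16168 tested. Without the batch term, which lets in Ctrl_HFD replicate 4, 17 were higher and 14 lower. Cdh6 was again higher, at 9.59 ± 1.53 CPM (SD, n = 5) against 0.21 ± 0.107 CPM (n = 3) in the Ctrl_HFD libraries of batch 1. Dok5, an adaptor of receptor tyrosine kinases, rose by 1.16 on the log2 scale (SE 0.18, adjusted p = 0.0144), Rps6ka6, a ribosomal S6 kinase gene, by 1.15 (SE 0.22) and Abhd18 by 0.58 (SE 0.10). Lower genes were led by Ptgds, the prostaglandin D2 synthase gene, at -1.92 (SE 0.28, adjusted p = 0.0144) and Scn10a at -1.10 (SE 0.18, adjusted p = 0.0144). They were followed by Mrvi1 at -1.18 (SE 0.18), the galectin gene Lgals3 at -0.74 (SE 0.13), Aldh3b2 at -1.48, Gucy2e at -2.58, Sbk3 at -0.59 and Sh3tc2 at -0.55. DESeq2 called 93 genes, limma-voom 126, and 1301 had an unadjusted p below 0.05, where chance gives about 808. The count fell to 2 without Ctrl_HFD replicate 1 or Ctrl_HFD replicate 3, to 3 without NaV1.5_HFD replicate 4, to 7 without NaV1.5_HFD replicate 2 and to 9 without NaV1.5_HFD replicate 3 or Ctrl_HFD replicate 2.

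Gene groups separated the genotypes on high-fat diet in 22 of 43 lists at camera's preset correlation. Proliferation genes were higher in NaV1.5 atria (24 measured, median 0.80, camera adjusted p = 2.73e-14; adjusted p = 0.185 with an estimated correlation). With edgeR 0 passed over all genes and 11 rose adjusted over the list alone, 12 had an unadjusted p below 0.05, and DESeq2 called 4 and limma-voom 5. Examples are Cdk1 at 1.36 (SE 0.28), Ccnb1 at 1.67 (SE 0.36) and Mki67 at 1.43 (SE 0.37), genes of the dividing cell. Extracellular matrix genes were higher (44 measured, median 0.30, camera adjusted p = 1.83e-08; adjusted p = 0.329 with an estimated correlation). Of these 4 passed adjusted over the list alone and 0 over all genes with edgeR, 8 at an unadjusted p below 0.05, 1 by DESeq2 and 2 by limma-voom. They were led by Postn at 0.87 (SE 0.22) and the collagen crosslinking enzyme gene Lox at 0.74 (SE 0.22). Fibroblast markers were higher too (13 measured, median 0.19, camera adjusted p = 0.0222; adjusted p = 0.301 with an estimated correlation), with 1 adjusted over the list alone. Clock genes were lower (19 measured, median -0.16, camera adjusted p = 3.9e-06; adjusted p = 0.185 with an estimated correlation). Of these 5 were lower adjusted over the list alone and 0 over all genes with edgeR, 6 at an unadjusted p below 0.05, 2 by DESeq2 and 3 by limma-voom. Hlf was at -0.61 (SE 0.13) and Ciart at -0.72 (SE 0.15). Erythroid markers, which come with red cell precursors or blood, were higher as well (7 measured, median 1.59, camera adjusted p = 1.23e-06; adjusted p = 0.301 with an estimated correlation), with 6 adjusted over the list alone. So were ventricular cardiomyocyte markers (median 0.48, camera adjusted p = 0.0201; adjusted p = 0.185 with an estimated correlation, fry adjusted p = 0.0207). Leaving out Ctrl_HFD replicate 1 gave the matrix list a median of 0.19, and leaving out Ctrl_HFD replicate 3 the clock list one of -0.10, and both still passed. Fibroblast markers failed without Ctrl_HFD replicate 1 (0.179) or NaV1.5_HFD replicate 2 (0.133), and ventricular markers without Ctrl_HFD replicate 1 (0.0588) or Ctrl_HFD replicate 2 (0.057). Without a low-count filter the ventricular markers passed with a median of 0.86.

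Ion channels and connexins were lower in NaV1.5 atria on high-fat diet (39 measured, median -0.20, camera adjusted p = 0.000503; adjusted p = 0.341 with an estimated correlation). Over all genes 1 rose and 1 fell, Scn10a, and adjusted over the list alone 2 rose, among them the potassium channel gene Kcnj2 by 0.41 (SE 0.11), and 1 fell. Targets of the fatty acid receptor PPAR were higher (22 measured, median 0.16, camera adjusted p = 0.00226; adjusted p = 0.341 with an estimated correlation). The fatty acid carrier gene Fabp4 at 0.64 (SE 0.14) and the pyruvate dehydrogenase kinase gene Pdk4 at 0.96 (SE 0.28) were the 2 that rose adjusted over the list alone. Over all genes 0 passed with edgeR (5 at an unadjusted p below 0.05, 1 by DESeq2, 2 by limma-voom). Without Ctrl_HFD replicate 3 the medians were near 0 and neither list passed, at -0.02 for channels (adjusted p = 0.111) and 0.03 for PPAR targets (0.119). Without Ctrl_HFD replicate 1 the channel list had a median of -0.32, and with limma-voom of -0.12.

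The genotype differences on the 2 diets share no library. Across 16168 genes their log2 differences correlated with Pearson's r = 0.335 and Spearman's rho = 0.328, a correlation over genes, which are not independent replicates. All 6 higher and all 8 lower genes of the high-fat diet had the same sign and an unadjusted p below 0.05 on regular diet, and Cdh6 and Scn10a passed on both.

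High-fat diet changed 182 of 16168 genes in NaV1.5 atria, of which 76 rose and 106 fell. Genes of the heat shock response were among those that rose. Hsp90aa1, a cytosolic chaperone gene (chromosome 12, 110690605 to 110702728, minus strand), went from 50.1 ± 6.71 CPM (SD, n = 4) to 109 ± 30.6 CPM (n = 5), a log2 difference of 1.13 (SE 0.18, adjusted p = 0.0124). Its cochaperone genes Chordc1 and Ahsa2 rose by 0.78 (SE 0.12) and 0.62 (SE 0.09), both with an adjusted p of 0.00833. Cd36, the fatty acid transporter gene, rose by 0.52 (SE 0.09), the sodium-calcium exchanger gene Slc8a1 by 0.61 (SE 0.10), the prolyl hydroxylase gene P4ha1 by 0.58 (SE 0.09) and the muscle actin-binding gene Xirp2 by 0.54 (SE 0.09). Ciart, a repressor of the circadian clock (chromosome 3, 95878503 to 95882251, minus strand), fell by 1.00 (SE 0.14, adjusted p = 0.00833), from 29.9 ± 5.43 CPM (n = 4) to 14.9 ± 2.02 CPM (n = 5). Ptgds fell by 1.62 (SE 0.26), the cold-inducible RNA-binding gene Cirbp by 0.64 (SE 0.11), and the glutathione transferase genes Gstm1 and Gstp1 by 0.44 (SE 0.08) and 0.38 (SE 0.07). Other named genes were Tmprss13, Retreg1, Tank and Xiap among the higher and Acy3, Gnb3, Lad1, Slc1a7, Sugp1, Mpst and Hes6 among the lower.

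The number of diet genes in NaV1.5 atria moved widely with single libraries and with GC content. Leaving out NaV1.5_RD replicate 3 left 4 genes, NaV1.5_HFD replicate 3 left 11, NaV1.5_HFD replicate 2 left 13, NaV1.5_RD replicate 2 left 19, NaV1.5_RD replicate 1 left 66 and NaV1.5_HFD replicate 5 left 89. Leaving out NaV1.5_HFD replicate 4 gave 506 and NaV1.5_RD replicate 4 gave 1138. Higher genes had a median GC content of 43.4% and lower genes 56.0%, against 49.7% over all genes, and with GC and length offsets 74 genes passed, 51 of them shared. Hsp90aa1, Chordc1, Ahsa2, Cirbp and Ciart were among those that passed with the offsets, and Tank, Xiap, Lad1, Gstp1 and Hes6 did not. DESeq2 called 828 genes and limma-voom 1970.

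By list, 8 of 43 passed camera at its preset correlation for the diet in NaV1.5 atria. Of 14 heat shock genes measured, 4 rose over all genes and 6 adjusted over the list alone (median 0.15, camera adjusted p = 0.000229; adjusted p = 0.37 with an estimated correlation, fry adjusted p = 0.0259). Among them were Hsph1 at 1.11 (SE 0.23) and Hspa4l at 0.41 (SE 0.10). Of 27 genes of the integrated stress and unfolded protein response, 2 rose over all genes, Hsp90b1 by 0.51 (SE 0.10) and Pdia4 by 0.48 (SE 0.12). Adjusted over the list alone 8 rose and 1 fell (median 0.18, camera adjusted p = 0.00101; adjusted p = 0.411 with an estimated correlation, fry adjusted p = 0.0382). Of 29 genes of fatty acid uptake and oxidation, 5 rose over all genes, and adjusted over the list alone 11 rose and 4 fell (median 0.08, camera adjusted p = 0.0149; adjusted p = 0.703 with an estimated correlation). The 5 were Cd36 and the mitochondrial genes Acadvl at 0.43, Etfdh at 0.38, Decr1 at 0.42 and Hadhb at 0.41. Fatty acid synthesis moved the other way (23 measured, median -0.21, camera adjusted p = 0.0361; adjusted p = 0.703 with an estimated correlation). Fasn, the fatty acid synthase gene, fell by 0.64 (SE 0.14) and the desaturase gene Fads1 by 0.35 (SE 0.08) over all genes, and 4 fell adjusted over the list alone. White adipocyte markers had a median of -2.24 in the same atria (11 measured, 9 below 0, camera adjusted p = 0.118), and adjusted over the list alone 2 fell and 1 rose. Of 19 clock genes, Ciart and Dbp fell over all genes and 6 fell adjusted over the list alone (median -0.12, camera adjusted p = 0.0149; adjusted p = 0.703 with an estimated correlation). Interferon response genes were higher (26 measured, median 0.31, camera adjusted p = 5.78e-06; adjusted p = 0.703 with an estimated correlation). Of these 10 rose adjusted over the list alone and 0 over all genes with edgeR (10 at an unadjusted p below 0.05, 5 by DESeq2, 7 by limma-voom). They included Zbp1 at 0.81 (SE 0.23) and Rsad2 at 0.82 (SE 0.24). Erythroid markers were higher in the same atria (7 measured, median 0.72, camera adjusted p = 0.0251; adjusted p = 0.703 with an estimated correlation). Ventricular cardiomyocyte markers passed fry alone (6 measured, median -0.53, fry adjusted p = 0.0295, camera adjusted p = 0.169).

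Single libraries and the choice of tool decided some of these lists. With limma-voom the fatty acid oxidation list did not pass and its median lay below 0 (-0.0108, adjusted p = 0.1). It also failed without NaV1.5_RD replicate 1 (median 0.05, adjusted p = 0.055), NaV1.5_HFD replicate 1 (0.02, 0.0872) or NaV1.5_HFD replicate 5 (0.05, 0.0603). It passed with a median of 0.12 without NaV1.5_RD replicate 3 or NaV1.5_HFD replicate 3 and of 0.03 without NaV1.5_RD replicate 4. The synthesis list had an adjusted p of 0.178 without NaV1.5_RD replicate 2, 0.175 without NaV1.5_RD replicate 3 (median -0.10), 0.125 without NaV1.5_HFD replicate 2, 0.0613 with all libraries in one fit and 0.108 with GC and length offsets (median -0.10). The clock list had 0.0593 without NaV1.5_RD replicate 2. It passed with a median of -0.08 without NaV1.5_RD replicate 3 and with the offsets, and near -0.20 without NaV1.5_RD replicate 4 and with limma-voom. Heat shock genes kept a call at a median of 0.07 without NaV1.5_HFD replicate 3, and interferon genes at 0.20 without NaV1.5_HFD replicate 2. Erythroid markers failed without NaV1.5_RD replicate 1 (0.155), NaV1.5_RD replicate 2 (0.114), NaV1.5_HFD replicate 2 (0.0861) or NaV1.5_HFD replicate 4 (0.141), and had a median of 1.46 without NaV1.5_RD replicate 4 and 1.33 with limma-voom.

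In control mice the same diet changed 0 of 16168 genes with edgeR, a test that recovered a 1.5-fold change for 36% of simulated genes. The simulation also held larger changes, which ease the adjusted threshold, so recovery where 0 genes pass may be lower. An unadjusted p below 0.05 was found for 1372, where chance gives about 808, and DESeq2 called 14 and limma-voom 69. The leading genes, none past the threshold, included some that rose in NaV1.5 atria, Xirp2 at 0.49 (SE 0.10), Chordc1 at 0.59 (SE 0.13) and Slc8a1 at 0.51 (SE 0.12). Others were the peroxisomal and mitochondrial fatty acid gene Ech1 at 0.69 (SE 0.13) and the integrin gene Itgb6 at 0.93 (SE 0.17). Lower were Cited1 at -0.88 (SE 0.17), Sugp1 at -0.38 (SE 0.09) and Cpt1a, the gate of mitochondrial fatty acid import, at -0.47 (SE 0.12). Stress response genes were higher as a list (27 measured, median 0.27, camera adjusted p = 1.48e-05; adjusted p = 0.255 with an estimated correlation). Mthfd2 at 0.93 (SE 0.23) and Atf5 at 0.36 (SE 0.11) were the 2 that rose adjusted over the list alone. Fatty acid oxidation genes were higher (29 measured, median 0.10, camera adjusted p = 0.00169; adjusted p = 0.667 with an estimated correlation). Of these 8 rose, Cd36 at 0.42 (SE 0.10) among them, and 2 fell, Cpt1a and Mlycd, adjusted over the list alone. Heat shock genes were higher (14 measured, median 0.11, camera adjusted p = 0.0148; adjusted p = 0.628 with an estimated correlation), Hsp90aa1 at 0.69 (SE 0.20), with 3 up adjusted over the list alone. Extracellular matrix genes were lower (44 measured, median -0.31, camera adjusted p = 4.2e-06; adjusted p = 0.628 with an estimated correlation), led by Fn1 at -0.56 (SE 0.20). PPAR targets were lower too (22 measured, median -0.21, camera adjusted p = 0.000518, and adjusted p = 0.628 with an estimated correlation), Creb3l3 at -1.82 (SE 0.59) among them. Creb3l3 gave a value in only 8 of the alternatives that leave out no single library, where Pdk4 gave one in 10. Markers of other cell types moved with these lists. Endothelial markers were lower (14 measured, median -0.13, camera adjusted p = 0.00643; adjusted p = 0.628 with an estimated correlation), as were neutrophil markers (5 measured, median -0.59, camera adjusted p = 0.0342; adjusted p = 0.628 with an estimated correlation) and white adipocyte markers (11 measured, median -1.32, camera adjusted p = 0.0342; adjusted p = 0.771 with an estimated correlation). Epicardial and mesothelial markers were higher (14 measured, median 0.39, camera adjusted p = 0.000242; adjusted p = 0.667 with an estimated correlation).

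In control mice too these calls hung on single libraries. Without Ctrl_HFD replicate 3 the adjusted p was 0.146 for the PPAR list and 0.14 for the heat shock list, and without Ctrl_HFD replicate 1 it was 0.0683 for the oxidation list. With limma-voom the oxidation list (0.0749) and the heat shock list (0.14) failed. Without Ctrl_RD replicate 3 the matrix list passed with a median of -0.14 and the heat shock list with 0.07, and without Ctrl_HFD replicate 1 or without the batch term the PPAR list passed, with -0.34 and -0.32. Endothelial markers failed without Ctrl_HFD replicate 1 (0.0503) or Ctrl_RD replicate 4 (0.0848), with limma-voom (0.133) and with GC and length offsets (0.152), and had a median of -0.205 without Ctrl_RD replicate 1. Epicardial markers failed without Ctrl_HFD replicate 1 (median 0.24, 0.0683). Adipocyte markers failed without Ctrl_HFD replicate 2 (0.307), Ctrl_HFD replicate 3 (0.146), Ctrl_RD replicate 1 (0.0674) or Ctrl_RD replicate 4 (0.214), with all libraries in one fit (0.156) and with the offsets (0.0739), and passed with a median of -0.845 without a low-count filter. Neutrophil markers failed with limma-voom (0.211) and without 6 libraries: Ctrl_HFD replicate 1 (0.0683), Ctrl_HFD replicate 2 (0.0647), Ctrl_HFD replicate 3 (0.0676), Ctrl_RD replicate 2 (0.064), Ctrl_RD replicate 3 (0.0543) and Ctrl_RD replicate 4 (0.123).

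The diet responses of the 2 genotypes share no library. Of the 76 genes that rose in NaV1.5 atria, 75 had the same sign in control mice and 49 an unadjusted p below 0.05 there; of the 106 that fell, 105 had the same sign and 64 such a p. The median log2 difference of the risen genes was 0.47 in NaV1.5 and 0.27 in control mice, and of the fallen genes -0.46 and -0.26. Since the genes were selected in NaV1.5 libraries, the smaller control values are no test of a difference. Over all genes r was 0.327 and rho 0.452, and 11393 of 16168 genes had the same sign. Log2 change also ran with GC content in both comparisons, with a rho of -0.462 in NaV1.5 and -0.396 in control mice, and with GC and length offsets, chosen after this trend was seen, r was 0.252.

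**Figure D3:**
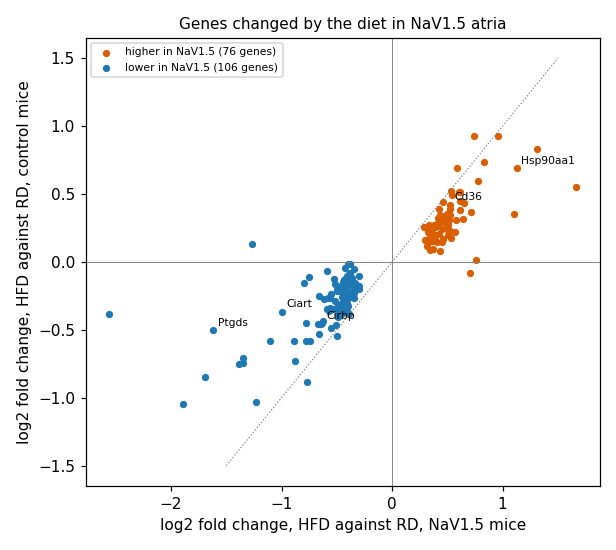
Log2 fold change of HFD against RD in NaV1.5 mice (x axis) and in control mice (y axis) for the 76 higher and 106 lower genes of the NaV1.5 comparison; each point is 1 gene and the dotted line marks equal change. In control mice 75 of the higher and 105 of the lower genes have the same sign.

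The test of the difference itself, diet by genotype, called 0 of 16168 genes with edgeR, and 0 with DESeq2 and with limma-voom. An unadjusted p below 0.05 was found for 366, fewer than the 808 that chance gives. With edgeR this test recovered a 1.5-fold change for only 18% of simulated genes. Larger changes in that simulation eased the adjusted threshold, so recovery where 0 genes pass may be lower. Among lists, 9 of 43 passed camera at its preset correlation. PPAR targets responded to the diet more positively in NaV1.5 than in control mice (median 0.17, camera adjusted p = 2.46e-05, and adjusted p = 0.675 with an estimated correlation). Among them were Pdk4 at 1.26 (SE 0.38) and Creb3l3 at 2.25 (SE 0.76). Of the alternatives that leave out no single library, 10 gave a value for Pdk4 and 9 for Creb3l3. Proliferation genes also responded more positively in NaV1.5 mice (median 0.42, camera adjusted p = 3.36e-05, and adjusted p = 0.675 with an estimated correlation), with Cdk1 at 0.85 (SE 0.38). However, without Ctrl_RD replicate 3 the median was 0.16 (adjusted p = 0.0564). Without NaV1.5_RD replicate 1 it was 0.67 and with limma-voom 0.27. The PPAR median was 0.28 without NaV1.5_RD replicate 3 and 0.10 with limma-voom. With the replicate number as a block, a fit that also left out the unnumbered libraries, the PPAR list failed (median 0.0124, adjusted p = 0.187). So did the proliferation list there (0.193, 0.315). Erythroid markers went the same way (median 1.21, camera adjusted p = 3.36e-05; adjusted p = 0.675 with an estimated correlation), with a median of 1.86 without NaV1.5_RD replicate 4. Clock genes responded more negatively (median -0.08, camera adjusted p = 0.0282; adjusted p = 0.675 with an estimated correlation), Ciart at -0.63 (SE 0.21). That call was lost without any of 7 libraries: NaV1.5_RD replicate 2 (0.147), Ctrl_RD replicate 3 (0.0564), NaV1.5_HFD replicate 2 (0.0521), Ctrl_RD replicate 4 (0.416, median -0.000666), NaV1.5_HFD replicate 3 (0.0747), Ctrl_HFD replicate 2 (0.0609) and Ctrl_HFD replicate 3 (0.0953). It was also lost without the batch term (0.0572), with limma-voom (0.0571) and with all libraries in one fit (0.108). Without NaV1.5_HFD replicate 1 or Ctrl_HFD replicate 1 it was kept, at medians of -0.14 and -0.17.

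The 7 genes of NAD metabolism followed here did not pass with edgeR in any comparison. Nmrk2, the muscle nicotinamide riboside kinase gene (chromosome 10, 81198170 to 81202051, minus strand), came nearest. It was at 21.1 ± 7.8 CPM (SD, n = 5) in NaV1.5_HFD against 9.85 ± 0.887 CPM (n = 4) in NaV1.5_RD, a log2 difference of 1.10 (SE 0.26, adjusted p = 0.0538). It passed without NaV1.5_HFD replicate 4 (adjusted p = 0.0209) or NaV1.5_RD replicate 4 (0.0452), with DESeq2 (0.00102), limma-voom (0.0128) or the stricter low-count filter (0.046). In the list of NAD synthesis and salvage (20 measured) Nmrk2 was the 1 that rose adjusted over the list alone. Of 25 measured NAD consumers 1 rose with the diet in NaV1.5 atria over all genes, Parp14 by 0.47 (SE 0.11, adjusted p = 0.0431). The diet difference of Nmrk2 was 0.43 (SE 0.28) in control mice, and the test between genotypes gave 0.67 (SE 0.38, adjusted p = 1). For the diet in NaV1.5 atria, Nampt, the salvage enzyme gene, was at 0.22 (SE 0.15), Nmrk1 at -0.15 (SE 0.14), the methyltransferase gene Nnmt at 0.13 (SE 0.19). The NAD-consuming genes Cd38, Parp1 and Sirt1 were at 0.20 (SE 0.12), -0.22 (SE 0.12) and 0.18 (SE 0.13). With NR, Cd38 was at -0.28 (SE 0.09, adjusted p = 0.226), Nnmt at 0.35 (SE 0.17) and Nmrk2 at 0.06 (SE 0.75).

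The second experiment asked what NR changed in NaV1.5 atria on high-fat diet. Within batch 3, 14 genes were higher and 56 lower with NR among 16482 tested, with the NR libraries of batch 2 informing the spread. An unadjusted p below 0.05 was found for 1829, where chance gives about 824. A fit of the batch 3 libraries alone called 18 genes, 7 higher and 11 lower, with 11 of the 18 shared. The RNA-binding protein gene Ro60 (chromosome 1, 143750790 to 143777068, minus strand) was at 26.8 ± 2.27 CPM (SD, n = 2) with NR and 44.4 ± 2.36 CPM (n = 5) with vehicle, a log2 difference of -0.73 (SE 0.08, adjusted p = 0.00186). Also lower were Lnpk, an organiser of the endoplasmic reticulum, at -0.83 (SE 0.10), the thioesterase gene Lypla1 at -0.73 (SE 0.09), and Scai at -0.79 (SE 0.11). The ubiquitin ligase genes Mib1 and Trim2 were at -0.48 (SE 0.07) and -0.56 (SE 0.09), and the others named are Impad1, Osbpl8, Yes1, Zfp971, Alg10b and Mir703. The short noncoding RNA gene Bc1 (chromosome 7, 144914470 to 144914637) was higher, at 41.6 ± 1.09 CPM (n = 2) against 11.9 ± 2.94 CPM (n = 5), a log2 difference of 1.81 (SE 0.20, adjusted p = 0.00415). So were Rpl23a, a gene with pseudogenes, at 0.52 (SE 0.07) and the phospholipase gene Pla2g2d at 1.60 (SE 0.26). Also higher were Folr2 at 0.75 (SE 0.14), Siglec1 at 0.73 (SE 0.15), Fcgr2b at 0.61 (SE 0.13), Il6ra at 0.70 (SE 0.14) and Arhgdib at 0.49 (SE 0.09). The other higher genes named are Prelp, Serping1, Mgp and the interferon-induced gene Oas2 at 0.87 (SE 0.17).

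In the 5 NR libraries of batch 2 most of the lower genes were not below vehicle. There Ro60 was at 81.9 ± 3.28 CPM (SD, n = 5), above vehicle, and only 11 of the 56 lower genes were below vehicle, against 12 of the 14 higher genes above it. That contrast is also one between batches and called 9851 genes. Without NR replicate 7 only 1 gene passed, which is not among the 70, with Ro60 at an adjusted p of 0.117 and Bc1 at 0.117. The count was 36 without vehicle replicate 1, 34 without NR replicate 2, 41 without vehicle replicate 3, 44 without vehicle replicate 4 and 33 without vehicle replicate 5. The lower genes had a median GC content of 39.2% and a median length of 6530 bases. For the higher genes these were 50.4% and 1490 bases, and over all genes 49.4% and 3150 bases. With GC and length offsets 15 genes passed, 12 of them shared, and DESeq2 called 237 and limma-voom 37.

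**Figure D4:**
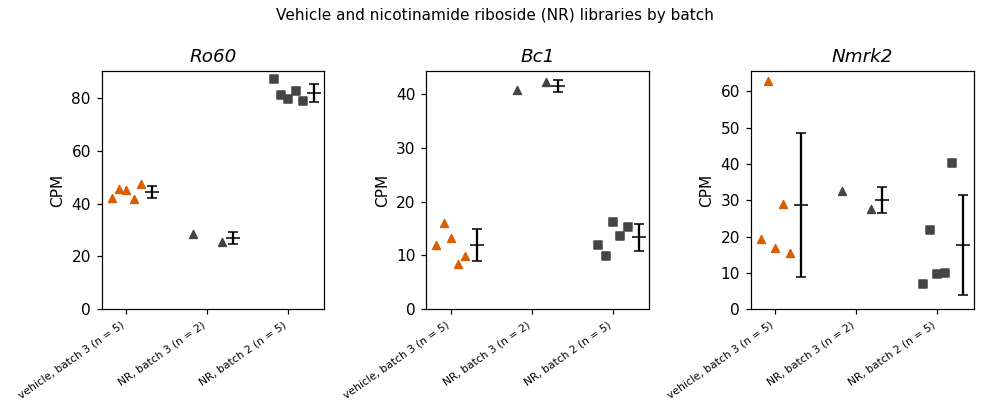
Normalised counts (CPM, y axes from 0) of Ro60, Bc1 and Nmrk2 in the vehicle libraries of batch 3 and the NR libraries of batch 3 and batch 2; each point is 1 library and the bar is the mean ± SD. Ro60 averages 44.4 CPM with vehicle, 26.8 CPM with NR in batch 3 and 81.9 CPM with NR in batch 2.

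Of 43 lists, 11 passed camera at its preset correlation for NR. Interferon response genes were higher (26 measured, median 0.31, camera adjusted p = 2.42e-06; adjusted p = 0.705 with an estimated correlation), with Oas2 the 1 that rose over all genes and adjusted over the list alone. Without NR replicate 7 that list's median was -0.0494 (adjusted p = 0.639), and without NR replicate 6 it was 0.54 and without the batch term 0.51. Macrophage markers were higher (18 measured, median 0.28, camera adjusted p = 9.3e-06; adjusted p = 0.68 with an estimated correlation), and passed with a median of 0.18 without NR replicate 7. Adjusted over the list alone 2 rose, Cd68 at 0.56 (SE 0.13) and the complement gene C1qc at 0.42 (SE 0.12), and 0 over all genes with edgeR (8 at an unadjusted p below 0.05, 1 by DESeq2, 0 by limma-voom). Fibroblast markers were higher (13 measured, median 0.19, camera adjusted p = 0.0128; adjusted p = 0.68 with an estimated correlation), but not without NR replicate 7 (median -0.0171, 0.556) or without the batch term (0.102). Immediate early genes, which respond to acute stimulation and to handling of tissue, were higher (20 measured, median 0.38, camera adjusted p = 9.3e-06; adjusted p = 0.68 with an estimated correlation). Klf4 was at 0.40 (SE 0.13) and Nr4a1 at 1.16 (SE 0.48), and 0 passed singly over all genes with edgeR or adjusted over the list alone (4 at an unadjusted p below 0.05, 0 by DESeq2 or limma-voom). That list had a median of 0.195 without NR replicate 7, and did not pass without the batch term (0.615). Mitochondrially encoded genes of the respiratory chain were lower (13 measured, median -0.20, camera adjusted p = 0.0128; adjusted p = 0.718 with an estimated correlation), with mt-Atp8 the 1 that fell, by 2.25 (SE 0.40). The mitochondrial list did not pass without vehicle replicate 1 (0.0849, median -0.14), vehicle replicate 2 (0.0571) or NR replicate 7 (0.949, median -0.04), nor without the batch term (0.96), with limma-voom (0.112) or with GC and length offsets (0.873). Its median was -0.35 without NR replicate 6. White adipocyte markers, from fat that adjoins the atria, lay higher with NR too (13 measured, median 2.11, camera adjusted p = 0.0222; adjusted p = 0.718 with an estimated correlation). They had a median of -0.776 without NR replicate 7 (0.692). They did not pass either without NR replicate 3 (0.0564), NR replicate 4 (0.0503), vehicle replicate 4 (0.0826) or vehicle replicate 5 (0.0687), with the stricter low-count filter (0.0789), limma-voom (median 1.12, 0.173) or the offsets (0.167).

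Whether NR moved the genes of the first experiment was tested on 4 sets, taken from libraries that do not enter the NR contrast. Of the 76 genes that rose with the diet, 32 were above and 44 below 0 with NR (median -0.0318, camera adjusted p = 0.28 over the 4 sets). Of 104 measured genes that fell, 40 were above and 64 below (median -0.0536, camera adjusted p = 0.28). For genotype on high-fat diet, where fewer genes passed, the sets were the 100 with the smallest p in each direction. Those higher in NaV1.5 had a median of -0.0613 (98 measured, camera adjusted p = 0.691) and those lower -0.0436 (98 measured, camera adjusted p = 0.28). None of the 4 sets passed with batch in the model, and with edgeR 0 of their genes passed singly. With 1 library left out the risen diet set passed, without NR replicate 6 (median -0.0721, adjusted p = 0.0335). The lower genotype set did not pass without vehicle replicate 2 (-0.0938, adjusted p = 0.056). Without the batch term, where NR libraries of batch 2 are set against vehicle of batch 3, the fallen diet set (-0.177, adjusted p = 3.86e-05) and the lower genotype set (-0.361, adjusted p = 8.96e-06) passed.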

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

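Except for the exchange of 2 labels, the tests of explanations and of outlying samples in this part were chosen only after the result was seen. The gene lists, and the alternatives other than the GC and length offsets, were fixed before the data were examined.

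The diet genes of NaV1.5 atria ran with GC content. Across genes, which are not independent replicates, log2 change and GC content had a rho of -0.462. With the offsets 51 of 182 genes passed in the same direction. That argues against GC content or length as the whole cause only as far as the offsets model them. The 131 others had a median change in the called direction of 0.436 before and 0.303 after (median SE 0.0944), so their calls ended as the change shrank, and in control mice with the offsets their median was 0.12, outside the -0.0352 to 0.0372 of 10000 random gene sets, with 120 of 131 of the same sign. Random gene sets carry no correlation between their genes, so these bounds may be too narrow. NaV1.5_RD replicate 4 does not make the calls, since 1138 genes passed without it. Of 100 splits of the NaV1.5 libraries, 4, the real one included, called at least the real 182 genes. That share, 0.04, argues against chance only weakly. The highest other split, which exchanges NaV1.5_RD replicate 4 and NaV1.5_HFD replicate 4, called 1544, which points to a structure of the samples. On genes of the diet in control mice these libraries scored 0.0168 and 0.031. That is between the other NaV1.5_RD (-0.172 to -0.16) and the other NaV1.5_HFD libraries (0.114 to 0.19). In principal components of the diet experiment NaV1.5_RD replicate 4 lay at 34.68 on PC1, above the highest NaV1.5_HFD library (26.52). On PC3 it had the lowest value, -31.59. Its counts differed from the other NaV1.5_RD libraries by 38.1 to 48.7 per gene in the chi-square test. Those libraries differed from each other by 6.93 to 12.5. Exchanged labels, intermediate samples and a library that stands apart for another reason cannot be told apart. A biological difference between these mice stays open, untested.

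Of the 56 genes lower with NR in batch 3, 51 had a higher mean in NR of batch 2 than in NaV1.5_HFD of batch 1, against 51.8% of all genes (exact binomial p = 4.01e-10 over genes, which are not independent replicates, so it measures no spread between samples). A preparation difference between batches may account for that, but treatment and experiment differ between these groups along with batch, so it stays open. With the offsets 8 of the 56 passed. GC content or length as the whole cause stays open. The 56 were chosen in the same libraries, and the offsets may remove such a bias only in part. NR replicate 7 as the whole cause stays open too. Without it the median of the 56 was -0.391 (-0.486 with all samples). That decides nothing, because NR replicate 6 and the same vehicle libraries entered their choice. In NR of batch 2, 11 of the 56 were below vehicle; treatment and batch are confounded there and cannot be told apart. Of 21 splits only the real one called 70 genes and the highest other called 6. That share, 0.0476, is the smallest that 21 splits can give. It argues against chance only weakly, and not against a difference in preparation.

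Cdh6 was on in all 21 NaV1.5 libraries (5.58 to 20 CPM) and near 0 in the 8 control libraries (at most 0.309 CPM). A change across the region is argued against by its 28 measured neighbours within 5 Mb, whose median absolute log2 difference was 0.104 on regular diet and 0.0882 on high-fat diet with 0 called by edgeR; the nearest gene, Drosha, was at 0.025 (SE 0.0884) and -0.119 (SE 0.0914). A transgene inserted at or near Cdh6 could give such a pattern and was not tested.

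For genotype on high-fat diet, 1 of 56 splits, the real one, called as many as 14 genes (highest other 4). That share, 0.0179, argues against chance but does not exclude it. For genotype on regular diet, 2 of 35 splits called as many as the real 2 genes (highest other 5), so the count alone does not exclude chance. Both genes, Cdh6 and Scn10a, passed in the same direction on high-fat diet in libraries that share none with these, which argues against chance for them. The real count was 0 for the diet in control mice (35 of 35 splits as large, highest other 3) and for the interaction (100 of 100, highest other 39). Every split is at least as large as 0, so the splits test nothing there.

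Of 72 groups of values, 6 held a sample far from the others, where chance marks about 1 in 20. Nmrk2 was at 62.7 CPM in vehicle replicate 2 (others 15.5 to 28.9), Cd38 at 18.3 CPM in Ctrl_HFD replicate 3 (16.5 to 16.6) and Ro60 at 16.2 CPM in the same library (19.8 to 20.4). The ventricular myosin gene Myl2 was at 193 CPM in NaV1.5_RD replicate 3 (8.98 to 34.2), 102 CPM in NaV1.5_HFD replicate 5 (5.15 to 8.86) and 80.2 CPM in Ctrl_RD replicate 1 (3.13 to 6.06). The 7 NR libraries were pooled over batches here, and none was marked for Myl2. Yet in the 2 NR libraries of batch 3, on which the NR contrast rests, Myl2 was at 0.723 and 326 CPM. With vehicle it was at 0.539 to 7.44 CPM.

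By the test of the interaction at camera's preset correlation, the diet response differed between genotypes in 9 lists, with median log2 differences (NaV1.5 minus control) of 0.166 for PPAR targets, 1.21 for erythroid markers, 0.416 for proliferation, 0.215 for endothelial markers, -0.126 for the nuclear respiratory chain, 0.0919 for extracellular matrix, 0.822 for neutrophil markers, -0.082 for clock genes and -0.0981 for the sarcomere. With an estimated correlation 0 of the 9 passed. The respiratory chain list failed without NaV1.5_RD replicate 4 (median 0.0449, adjusted p = 0.46), Ctrl_HFD replicate 1 (-0.0213, 0.788) or Ctrl_RD replicate 3 (-0.0668, 0.252), without the batch term (0.0572), with limma-voom (-0.00814, 0.836) and with the offsets (-0.0651, 0.109), and was at -0.191 without Ctrl_HFD replicate 3. The matrix list failed without Ctrl_RD replicate 3 (0.0155, 0.56), NaV1.5_RD replicate 4 (0.0351, 0.913) or Ctrl_HFD replicate 1 (0.0694, 0.209) and with limma-voom (0.0344, 0.826). It passed without NaV1.5_RD replicate 1 (0.181), NaV1.5_RD replicate 3 (0.154), NaV1.5_HFD replicate 1 (0.142), Ctrl_RD replicate 4 (0.186), Ctrl_HFD replicate 2 (0.174), Ctrl_HFD replicate 3 (0.235) or the batch term (0.0607). Endothelial markers failed without Ctrl_RD replicate 3 (0.0564), and neutrophil markers without Ctrl_RD replicate 3 (0.0564) or NaV1.5_RD replicate 3 (0.0708) and with limma-voom (0.0712), with a median of 1.25 without NaV1.5_RD replicate 4. The sarcomere list failed without NaV1.5_RD replicate 1 (0.0541), NaV1.5_RD replicate 2 (0.069), NaV1.5_HFD replicate 2 (0.162), NaV1.5_HFD replicate 3 (0.053), NaV1.5_HFD replicate 4 (0.0633), Ctrl_RD replicate 3 (0.292), Ctrl_RD replicate 4 (0.156) or Ctrl_HFD replicate 3 (0.0814), without the batch term (0.254) and with limma-voom (0.0952), and passed at -0.0639 without NaV1.5_RD replicate 3. In the NR libraries of batch 2, which carry no weight in the NR contrast, the brown fat gene Ucp1 reached 36.8 CPM in replicate 2 (vehicle 0 to 0.0472) and the fat cell gene Adipoq 24.3 CPM in replicate 4 (vehicle 0.0474 to 2.22).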

How the results depend on the processing

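The offsets for GC content and length were chosen only after the trend was seen; all other alternatives here were fixed before the data were examined. Of 2433 values of named genes with 1 library left out, 2139 kept their side of the threshold, 277 no longer passed, 17 newly passed and 0 reversed with a pass in either fit; under the other alternatives the numbers were 2091, 129, 127 and 43 of 2390. Counting values that passed in neither fit, 53 and 78 changed sign. For 27 lists, those described other than most marker lists and the lists of the observations, they were 241, 28, 0 and 2 of 271, and 226, 70, 0 and 5 of 301. With 1 library left out, genotype on regular diet called 1 to 5 genes, genotype on high-fat diet 2 to 14, the diet in NaV1.5 mice 4 to 1138 and NR 1 to 66; 59 to 78 lists passed, and the set medians under NR ran from -0.0721 to 0.0206 (diet, rose), -0.0785 to -0.029 (diet, fell), -0.141 to 0.00712 (genotype, rose) and -0.097 to -0.0199 (genotype, fell). The cause was not tested for any changed result here except where fewer or other samples were used.

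In the order genotype on regular diet, genotype on high-fat diet, diet in NaV1.5, diet in control mice, NR, counts that moved were as follows. Without a low-count filter they were 10, 43, not moved, 5 and 140. Without the batch term genotype on high-fat diet gave 31, diet in control mice 1 and NR 4392. DESeq2 gave 27, 93, 828, 14 and 237, and limma-voom 13, 126, 1970, 69 and 37. With all 29 libraries in one fit genotype on high-fat diet gave 9, diet in NaV1.5 732 and NR 27. With GC and length offsets diet in NaV1.5 gave 74, diet in control mice 1 and NR 15. Batch 3 alone gave 18 for NR, and NR of batch 2 against vehicle 9851. With an estimated correlation 0 lists passed of 258 tests, against 70, and with fry 5. Without the batch term the fallen diet set had a median of -0.177 under NR (adjusted p = 3.86e-05) and the lower genotype set -0.361 (8.96e-06), and both passed.

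With the replicate number as a block, genotype on regular diet called 1 gene, genotype on high-fat diet 8 and diet in NaV1.5 27, and NR, with the block in place of the batch term, 9694. In the diet experiment this fit also left out the libraries without a number in their titles, Ctrl_RD replicate 1 and NaV1.5_RD replicate 4. Counts and medians given with the block there therefore do not show the effect of the block alone. In the diet experiment the numbers show no pairing of the samples. Same-numbered libraries had correlated deviations above 0.1 in 4 of 16 pairs (median r -0.031), and differently numbered libraries in 12 of 56 (0.012). For the NR experiment these were 3 of 5 pairs (0.116) and 10 of 30 (-0.0099). With only 5 same-numbered pairs, pairing is not decided there.

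For the named genes and these 27 lists, where a value passed in either fit, the directions that reversed all concern NR (camera's direction for lists). Medians of passing lists also turned sign in other comparisons, none with a pass. The fatty acid oxidation list for the diet in NaV1.5 lay below 0 with the block (-0.00816, adjusted p = 0.144) and with limma-voom (-0.0108, 0.1), and the ion channel list for genotype on regular diet above 0 with the block (0.0326, 0.972). For the interaction the nuclear respiratory chain was at 0.0492 with the block and 0.0449 without NaV1.5_RD replicate 4, and matrix at -0.00663 with the block. For genotype on high-fat diet the interferon list was at -0.00479 without the batch term and the nuclear respiratory chain at -0.00519 without Ctrl_HFD replicate 3. Among other lists under NR, white adipocyte (-0.776), epicardial (-0.257), fibroblast (-0.0171) and NADPH oxidase (-0.0163) lists turned without NR replicate 7. Heat shock did without the batch term (-0.184), in NR of batch 2 (-0.333, adjusted p = 0.0437) and with the block (-0.315, 0.0285), and stress response in the last 2 (-0.0191 and -0.00916). Without the batch term Ro60 was at 0.578, Lypla1 0.00264, Scai 0.799, Mib1 0.299, Mir703 0.549, Impad1 0.0945, Yes1 0.225, Zfp971 1.15, Trim2 0.145 and mt-Atp8 0.0714. In NR of batch 2 against vehicle Siglec1 was at -0.152, Ro60 0.871, Lnpk 0.0726, Lypla1 0.202, Scai 1.13, Mib1 0.507, Mir703 0.988, Impad1 0.26, Yes1 0.437, Zfp971 1.51, Trim2 0.335, Cd38 0.595, mt-Atp8 0.448, mt-Atp6 0.55, Nr4a1 -0.891, Egr2 -1.03, Ier3 -0.502, the immediate early list -0.206 and the mitochondrially encoded list 0.155. With the block and no batch term they were Siglec1 -0.129, Ro60 0.885, Lnpk 0.0884, Lypla1 0.216, Scai 1.14, Mib1 0.521, Mir703 1.02, Impad1 0.274, Yes1 0.452, Zfp971 1.52, Trim2 0.348, Cd38 0.611, mt-Atp8 0.39, Nr4a1 -0.822, Egr2 -0.903, Ier3 -0.476, and the same lists -0.153 and 0.173. Without NR replicate 7 the interferon response list was at -0.0494 (up to 0.543 without NR replicate 6) and the list of the mitochondrially encoded respiratory chain at -0.0418 (down to -0.349 without NR replicate 6), and with the offsets the latter was at 0.00299.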

Other observations

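Except for the offsets, no test in this part was chosen after its result was seen; the gene lists were fixed before the data were examined, and those described here were picked from the lists that passed.

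Markers of several cell types stood higher in NaV1.5 than in control atria on high-fat diet. Endothelial markers had a median log2 difference of 0.20 (14 measured, camera adjusted p = 8.98e-06; adjusted p = 0.185 with an estimated correlation), with 2 up adjusted over the list alone. Macrophage markers were at 0.26 (18 measured, camera adjusted p = 4.15e-05; adjusted p = 0.329 with an estimated correlation), lymphocyte markers at 0.39 (15 measured, camera adjusted p = 0.0126; adjusted p = 0.363 with an estimated correlation) and neutrophil markers at 0.98 (5 measured, camera adjusted p = 0.00515; adjusted p = 0.301 with an estimated correlation). The lymphocyte list failed without Ctrl_HFD replicate 2 (0.119), NaV1.5_HFD replicate 2 (0.0537), NaV1.5_HFD replicate 4 (0.142) or the batch term (0.229). Genes of the sarcomere had a median of -0.13 (22 measured, camera adjusted p = 0.00244; adjusted p = 0.301 with an estimated correlation), and of atrial identity -0.11 (26 measured, camera adjusted p = 0.0135; adjusted p = 0.282 with an estimated correlation). The sarcomere list was at -0.08 without the batch term and still passed. The atrial list had a median of -0.00446 without Ctrl_HFD replicate 3 (0.25).

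Mitochondrially encoded genes of the respiratory chain were higher on high-fat diet in both genotypes. The median was 0.33 in control mice (11 measured, camera adjusted p = 1.54e-05; adjusted p = 0.628 with an estimated correlation) and 0.27 in NaV1.5 mice (11 measured, camera adjusted p = 0.0149; adjusted p = 0.703 with an estimated correlation). With GC and length offsets, chosen after a trend with GC content was seen, neither passed, at 0.11 (0.164) in control and 0.05 (0.642) in NaV1.5 mice. In NaV1.5 mice it failed without NaV1.5_RD replicate 1 (0.0755) or NaV1.5_HFD replicate 5 (0.0523), and in control mice its median was 0.14 without Ctrl_HFD replicate 1. With NR, epicardial and mesothelial markers were at 0.36 (14 measured, camera adjusted p = 0.0222; adjusted p = 0.721 with an estimated correlation) and heat shock genes at 0.25 (14 measured, camera adjusted p = 0.000965; adjusted p = 0.705 with an estimated correlation). The epicardial list failed without NR replicate 7 (median -0.257, 0.064; 0.778 without NR replicate 6), vehicle replicate 2 (0.0736), vehicle replicate 4 (0.125) or vehicle replicate 5 (0.0655) and with the offsets (0.167), and the heat shock list without the batch term (-0.184, 0.323). In NR of batch 2 against vehicle, a contrast between batches too, heat shock genes were lower (-0.333, adjusted p = 0.0437).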
